A study of Gallus gallus with 6 samples.

How the data were processed

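RNA sequencing was carried out on lungs of White Leghorn chicken embryos at embryonic day 5 (E5) and embryonic day 6 (E6). Per the labels' protocols, each library was made from RNA of a pool of 6 lungs, extracted with a QIAGEN kit for fibrous tissue, and libraries were made with the PrepX RNA-Seq kit of WaferGen. The series design describes 3 biological replicates at each stage.

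The authors deposited 1 table of raw counts per library, with whole-number read counts for 17108 versioned Ensembl chicken gene identifiers and no normalization. The submitters' processing notes name Bowtie 1.1.1, cutadapt 1.6, TopHat 0.9, HTSeq, DESeq2 and R 3.2.1, and list DESeq2 with both 2.1.8.3 and 1.8.2 as its version. The same notes name the genome builds galGal4 (chicken) and mm10 (mouse) without saying what each was used for. The strand setting of the counting, the annotation release and the handling of reads that fit several genes are not given in the sources used here. Without the strand setting, reads of a gene cannot be told from reads of a gene that overlaps it on the other strand, and reads shared with a near-identical copy may be split between genes. The tables hold no entries for unassigned reads. The 6 tables list the same identifiers in the same order, and no 2 libraries agreed within sampling noise (chi-square test of their counts).

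The files do not pair the identifiers with gene names. The reference table used here, of 25635 chicken genes, gave an Ensembl identifier for 0 of them, so it could not give names to any of the 17108 identifiers. The 23 gene lists fixed before the data were examined hold gene symbols and were therefore not analysed here; this says nothing about their genes. The rule fixed beforehand for which genes to name needed gene symbols and could not be applied either. The identifiers named in the results follow a rule chosen after the data were seen: the 2 in each direction with the smallest adjusted p in the fit with the replicate block that were also called from replicates 2 and 3 alone, with ties settled by the unadjusted p.

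Total counts ranged from 10059547 to 12993894 in replicates 2 and 3 and were 585803 and 509443 in the replicate 1 libraries of E5 and E6. Levels are given as CPM, the count of a gene scaled to the library total. A count of 0 allows up to 3 counts, which is 5.12 CPM in E5 replicate 1, 5.89 CPM in E6 replicate 1 and at most 0.298 CPM in each of the other 4 libraries. These limits cover counting error only.

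E6 was compared with E5 by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM normalization, genes kept by filterByExpr), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are E6 over E5, as log2 values. Standard errors (SE) are the size of the log2 fold change divided by the square root of the F statistic. The fit fixed before the data were examined used all 6 libraries and no replicate block, and a fit with the replicate number as a block was fixed beside it. Whether replicate numbers pair the libraries was checked from each library's deviation from its stage mean (log2 CPM, prior count 2). The correlation of these deviations between the E5 and E6 libraries of a number was 0.86 for number 1, 0.83 for number 2 and 0.84 for number 3, all above 0.1, so the numbers were taken as pairing the libraries. The pairing comes from the data, since the labels do not say what a number stands for. The values for numbers 2 and 3 come mostly from replicate 1 standing apart, since libraries of different numbers among these gave 0.82 and 0.80, hardly less. With replicates 2 and 3 only, the correlation was 0.35 for the same number and -0.35 across numbers. With 2 libraries per stage this is a single value, and by itself weak evidence that these numbers pair. The chi-square per degree of freedom between 2 libraries was 7.43 within number 2 and 5.00 within number 3. It was 11.6 to 15.4 for the other pairs of these 4 libraries, pairs of the same stage included. These values argue for numbers 2 and 3 pairing the libraries. A fit of replicates 2 and 3 with the same block was added after the data were seen.

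The fits were tested on simulated counts with 200 genes changed by a known fold. Each gene's mean was taken from the libraries of a replicate number, averaged over the stages, and its spread from the fit with the block. Every simulated change was given to the E6 library of each number, replicate 1 included where all 6 libraries were simulated. The shares and false calls hold for such changes only. They also hold only if the spread that edgeR estimated is right, since the counts were simulated with it. Whether replicate 1 of the data carries the stage differences stayed open, so those for 6 libraries may not hold for the data. In the simulation of the 6 libraries with the replicate block (11683 genes), 56.7% of the 1.5-fold, 77.6% of the 2-fold and 95.5% of the 4-fold changes were called, with 3 false calls. In that of replicates 2 and 3 with the block (11784 genes), these shares were 58.2%, 80.6% and 97.0%, with 7 false calls. In that of the 6 libraries without a block (11683 genes), 0 of the 200 changed genes were called.

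The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile normalization, library size alone, no filter beyond 1 count in any library, a filter at a mean of 5 CPM, a test against a fold of 1.5, the replicate block, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.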

Results

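The data comprised 6 libraries of embryonic chicken lung, 3 from E5 and 3 from E6, each from a pool of 6 lungs. The series title concerns the remodelling of extracellular matrix as the airways branch, and the question of the comparison was which transcripts changed from E5 to E6. The E5 libraries held 585803, 12993894 and 10855572 counts in replicates 1 to 3, and the E6 libraries held 509443, 10449717 and 10059547. Of the 17108 gene identifiers, 2073 had no count in these 6 libraries. Between 13649 and 13822 genes had a count in each library of replicates 2 and 3, against 9703 in E5 replicate 1 and 9149 in E6 replicate 1. The files do not pair the identifiers with gene names, so results are given by identifier and by number of genes, and gene groups such as matrix proteases or epithelial markers were not analysed here.

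**Figure D1:**
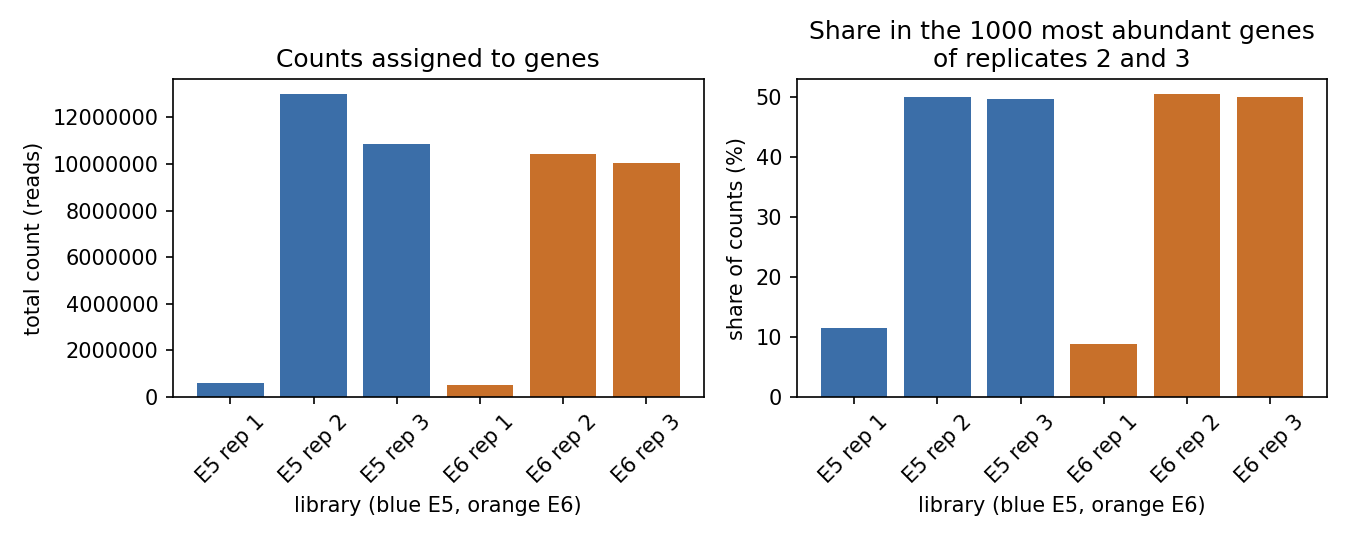
Total counts per library (left) and the percentage of each library's counts that fell in the 1000 genes most abundant in replicates 2 and 3 (right), 1 bar per library, E5 in blue and E6 in orange. The replicate 1 libraries have 585803 and 509443 counts and at most 11.5% of them in those genes, against at least 49.7% in the other 4 libraries.

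The replicate 1 libraries of both stages held a different set of abundant genes from the other 4. Of the 100 genes with the highest counts in E5 replicate 2, 3 were among the 100 highest in E5 replicate 1 and 3 in E6 replicate 1, against 89 to 93 in the remaining libraries. The gene with the highest total in replicates 2 and 3 had between 126490 and 184022 counts in each of them, and 478 and 141 counts in replicate 1 of E5 and E6. In reverse, the gene with the highest count in E5 replicate 1 had 55907 counts there and 55156 in E6 replicate 1, and at most 2 in each of the other libraries. A second gene had 33467 and 41206 counts in replicate 1 and 0 in the other 4. Genes with 0 counts in replicates 2 and 3 took 12.1% of the counts in E5 replicate 1 and 14.8% in E6 replicate 1. Of the 6928 genes with over 1000 counts summed over replicates 2 and 3, 440 had none in either replicate 1 library.

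The correlation of log2 CPM across genes was between 0.990 and 0.994 for the 6 pairs of libraries within replicates 2 and 3. The 2 highest values were between E5 and E6 of the same number, 0.9943 for replicate 2 and 0.9936 for replicate 3. Replicates 2 and 3 of the same stage gave 0.9925 at E5 and 0.9905 at E6. The correlation was 0.85 between the 2 replicate 1 libraries and between 0.47 and 0.56 for the 8 pairs of a replicate 1 library with another. Genes are not independent replicates, so these values describe the libraries only. The 10 genes with the highest counts took 28.3% of E5 replicate 1 and 33.0% of E6 replicate 1, and between 4.43% and 4.83% of the other libraries.

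**Figure D2:**
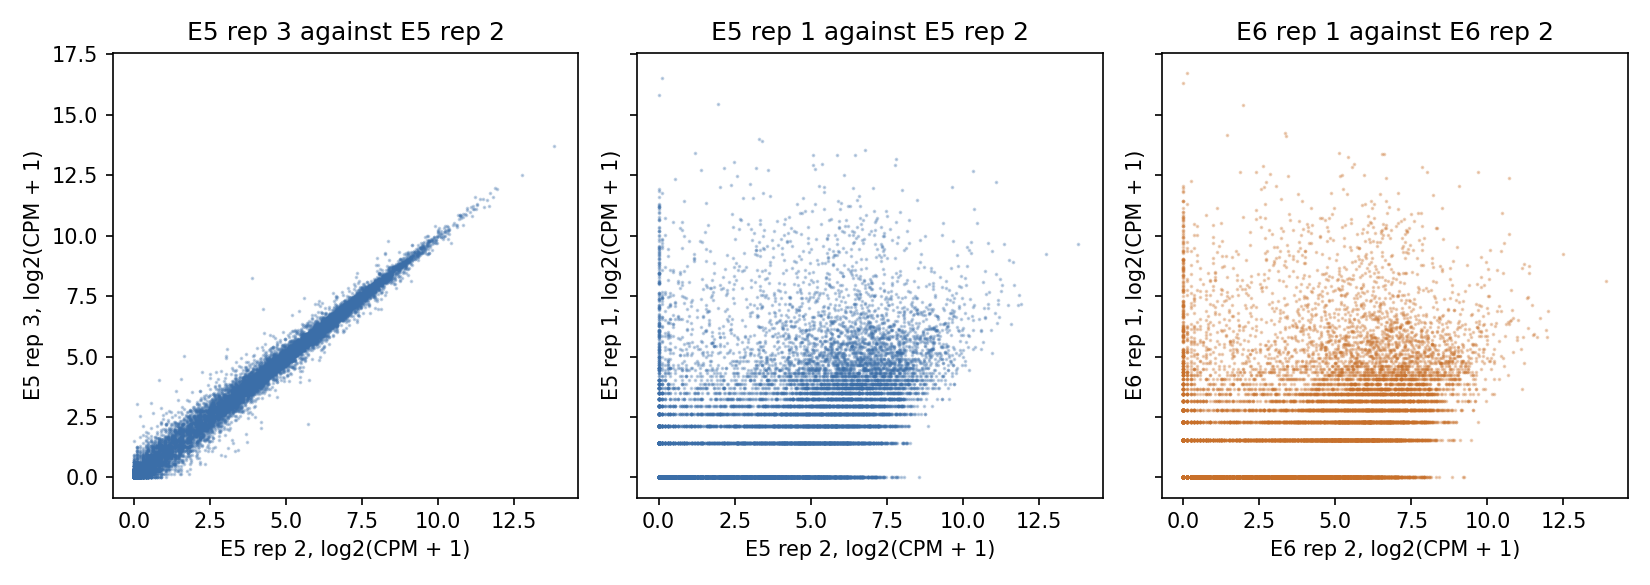
Each point is a gene, placed by its log2(CPM + 1) in 2 libraries of a stage. E5 replicate 3 follows E5 replicate 2 closely (left), whereas replicate 1 departs from replicate 2 at E5 (middle) and at E6 (right).

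From E5 to E6, ENSGALG00000022295.2 fell and ENSGALG00000008239.4 rose in the fit of 6 libraries that compared the stages within replicate numbers. They had the smallest adjusted p of each direction among its calls that were also called from replicates 2 and 3 alone. In the fit of 6 libraries 28 of 11683 genes changed, 14 higher and 14 lower in E6, and 12 of them by at least 2-fold. The fit fixed beforehand, without the replicate block, called 0 of the same 11683 genes in edgeR. It also called 0 of the 200 changed genes in simulated counts, so its 0 does not tell whether the stages differ. Replicates 2 and 3 alone with the block, a fit added after the data were seen, gave 152 of 11784 genes, 75 higher and 77 lower in E6. Of the 28 genes, 26 were among these 152, which is no independent check, since both fits hold the same 4 libraries of replicates 2 and 3.

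ENSGALG00000022295.2 stood at 28.0 ± 0.82 CPM at E5 and 8.15 ± 0.43 CPM at E6 (SD, n = 2, replicates 2 and 3), and had 0 counts in both replicate 1 libraries, where a count of 0 allows up to 5.12 and 5.89 CPM. Its log2 fold change with the replicate block was -1.76 (SE 0.22, edgeR adjusted p = 4.8e-11), which is 3.39-fold lower at E6. With 0 counts in replicate 1, this change rests on pairs 2 and 3. From replicates 2 and 3 alone without the block it was also -1.76, with an edgeR adjusted p of 0.20. ENSGALG00000007731.4 fell from 22.4 ± 3.25 CPM to 7.24 ± 1.53 CPM (SD, n = 2), with a log2 fold change of -1.41 (SE 0.24, edgeR adjusted p = 1.3e-05). Its replicate 1 libraries went the other way, with 1 count at E5 and 8 at E6, and without the block its log2 fold change was 0.18. With the block and 6 libraries its log2 fold change was -0.44 (SE 1.08) in DESeq2 and -0.68 (SE 0.80) in limma-voom, so its size depended on the test.

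ENSGALG00000008239.4 rose from 14.3 ± 0.63 CPM at E5 to 34.5 ± 18.2 CPM at E6 (SD, n = 2). Its log2 fold change with the block was 1.24 (SE 0.19, edgeR adjusted p = 9.3e-07). The E6 pools differed, with 47.4 CPM in replicate 2 and 21.6 CPM in replicate 3. The SE of 0.19 hardly takes in this difference between pairs. The log2 fold change was 0.79 without E5 replicate 2 and 1.94 without E5 replicate 3. ENSGALG00000015914.4 rose from 5.53 ± 1.95 CPM to 17.1 ± 3.91 CPM (SD, n = 2), with a log2 fold change of 1.45 (SE 0.26, edgeR adjusted p = 4.4e-05). In replicate 1 it had 9 counts at E5 and 2 at E6, and without the block its log2 fold change was -0.058. With the block and 6 libraries, DESeq2 and limma-voom called none of these 4 genes. Their log2 fold changes in DESeq2 and limma-voom were -1.70 (SE 0.50) and -1.39 (SE 0.42) for ENSGALG00000022295.2, 1.46 (SE 0.65) and 1.55 (SE 0.43) for ENSGALG00000008239.4, and 0.93 (SE 0.77) and 0.87 (SE 0.63) for ENSGALG00000015914.4. In the test against a fold of 1.5 ENSGALG00000022295.2 alone stayed past the threshold.

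None of the 4 stayed past edgeR's threshold when any one library of replicate 2 or 3 was left out, which leaves replicate 1 and 1 other pair to compare. The log2 fold change of ENSGALG00000022295.2 stayed between -1.78 and -1.74 in these fits, while its SE rose from 0.22 to at least 0.76. That of ENSGALG00000007731.4 was -0.995 without E5 replicate 2 and -1.02 without E6 replicate 2, and -0.40 and -0.44 without E5 and E6 replicate 3. That of ENSGALG00000008239.4 was 0.79 and 0.81 without E5 and E6 replicate 2, and 1.94 without either library of replicate 3. For ENSGALG00000015914.4 it lay between 0.79 and 0.98. From replicates 2 and 3 alone with the block, limma-voom called all 4 and DESeq2 all but ENSGALG00000008239.4.

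**Figure D3:**
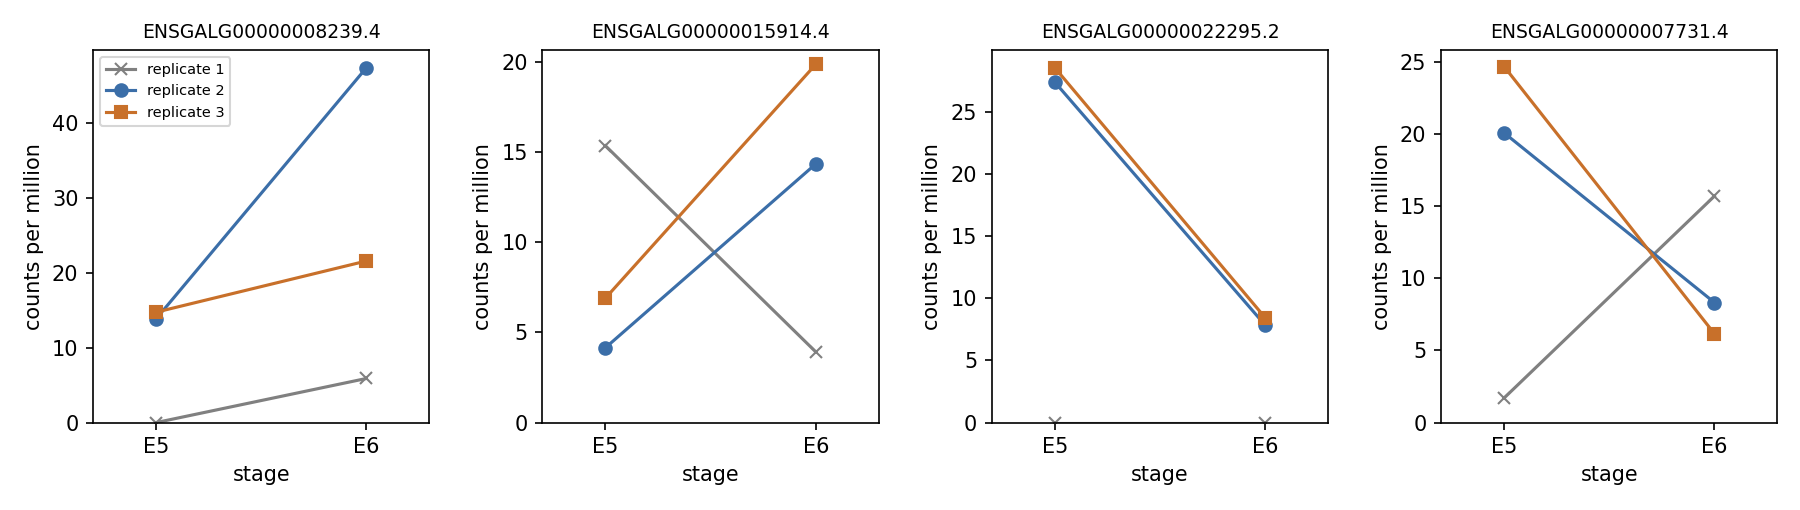
CPM of the 4 identifiers at E5 and E6, with a line joining the libraries of each replicate number. Replicates 2 and 3 move the same way in every panel, and replicate 1 (grey crosses, 0 to 9 counts) moves the other way for ENSGALG00000015914.4 and ENSGALG00000007731.4.

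Among the 152 genes called from replicates 2 and 3, the median size of the change was 0.57 on the log2 scale, and 38 changed by at least 2-fold, 17 higher and 21 lower in E6. For 88.2% of the genes tested, the 95% interval of the fold change lay within 2-fold in either direction. With 2 pairs these intervals borrow spread from other genes and can hardly take in a difference between the pairs. ENSGALG00000008239.4, whose pairs differed, had an SE of 0.16 in this fit. The intervals thus do not exclude wider changes. From the same 4 libraries with the block, limma-voom called 114 genes and DESeq2 9. Without the block edgeR called 0 of these genes, with 303 at an unadjusted p under 0.05, while DESeq2 called 4 and limma-voom 0.

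Without the block and with 6 libraries, 37 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 and limma-voom called 0, with 33 and 2 such genes. The biological coefficient of variation was 89.0% in that fit, which takes in the difference between replicate 1 and the rest, and 6.51% with the block. With the block and 6 libraries, DESeq2 and limma-voom called 0 genes, with 160 and 128 at an unadjusted p under 0.05. In edgeR with the block, 558 genes had an unadjusted p under 0.05, fewer than the 584 that chance alone gives, against 1070 with 589 by chance in replicates 2 and 3 alone. Of the 28 edgeR calls, 15 had the direction of pairs 2 and 3 in pair 1 too. No minimum count in replicate 1 was set for this tally. Genes with no counts there, such as ENSGALG00000022295.2, have no direction in pair 1 and fall among the rest. Leaving out the E5 or the E6 library of replicate 2 gave 4 calls and of replicate 3 gave 2, all higher in E6, and 0 of the 28 genes were among them. Leaving out that of replicate 1 gave 156 and 157 calls, each with 26 of the 28 genes.

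**Figure D4:**
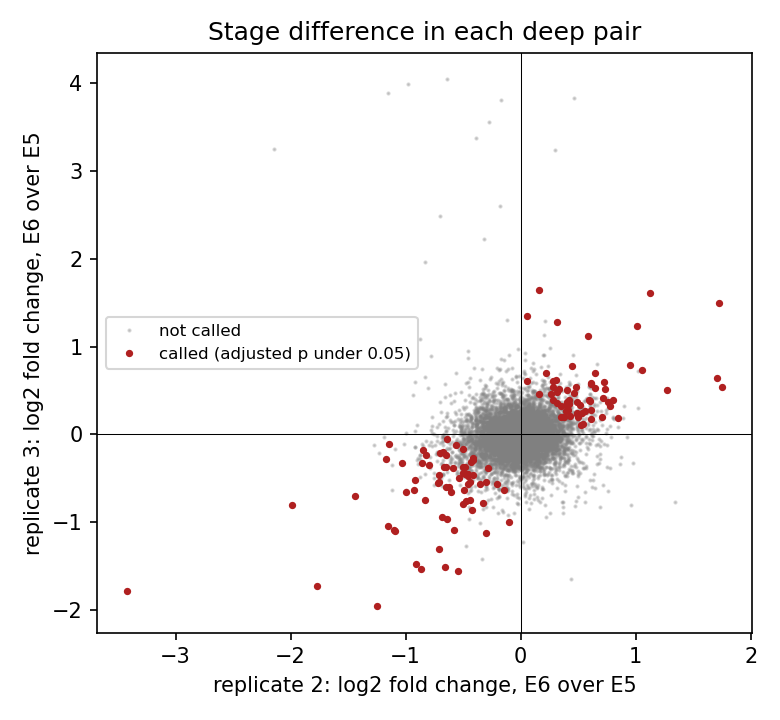
Log2 fold change of E6 over E5 in replicate 2 (horizontal) and replicate 3 (vertical) for each gene with a mean of at least 5 CPM in the 4 libraries of those numbers. Genes called from replicates 2 and 3 with the replicate block (red) lie along the rising diagonal, which follows largely from how they were called, and of all 9796 genes shown 53.2% have the same sign in both pairs.

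Across the 9796 genes with a mean of at least 5 CPM in replicates 2 and 3, the fold changes of pair 2 and pair 3 had a Pearson correlation of 0.13 and a Spearman correlation of 0.11. Those of pair 1 had a Pearson correlation of -0.04 with pair 2 and of 0.01 with pair 3. At least 10 counts were reached by 3309 genes in E5 replicate 1 and by 2563 in E6 replicate 1. Such low counts by themselves weaken any correlation with pair 1. These correlations are across genes, which are not independent replicates.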

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

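The planned comparison without a block gave 0 genes under every alternative test, normalization and filter and without each library in turn. In edgeR it also called 0 of the 200 changed genes in simulated counts, so the 0 does not tell whether the stages differ. Adding the replicate block gave 28. Leaving out both replicate 1 libraries, chosen after seeing the data, gave in edgeR 0 without and 152 with the block. With the block and 6 libraries, the normalizations and filters gave 26 to 33 genes, DESeq2 and limma-voom gave 0, the test against a 1.5-fold change gave 1, no block gave 0, replicates 2 and 3 alone gave 152, and leaving out single libraries gave 2 to 157. With the block and replicates 2 and 3, normalizations and filters gave 136 to 153 and limma-voom 114, while DESeq2 gave 9, the test against 1.5-fold gave 8 and no block gave 0 in edgeR and limma-voom and 4 in DESeq2. The cause of these differences between tests was not tested. The median of all genes moved by under 0.1 on the log2 scale with each normalization. The 4 named identifiers had 64 values under the alternatives to the fit with the block and 6 libraries. Of these, 62 kept their direction and 33 stayed past the threshold. The exceptions in direction came without the block, where ENSGALG00000015914.4 was at -0.058 and ENSGALG00000007731.4 at 0.18 on the log2 scale. The 33 came from edgeR's normalizations and filters, from fits without 1 or both replicate 1 libraries, and, for ENSGALG00000022295.2 only, from the test against a fold of 1.5. The identifiers were chosen as also called from replicates 2 and 3 alone, so passing without replicate 1 follows from that choice. With the block, leaving out a library also takes the comparison away from its partner, and for replicates 2 and 3 no residual spread is then left, so that was not run. The 23 gene lists and the removal of globin and mitochondrial genes were not run, since the reference used here held 0 Ensembl identifiers to take names from. Depth limits replicate 1: 1 read of 585803 is 1.71 CPM.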

Other observations

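The tests on why replicate 1 stands apart and the set of genes that differed in pair 3 were chosen after those results were seen; the splits of the libraries, the direction of called genes in replicate 1 and the comparison of replicates 2 and 3 were set before their results were seen.

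More genes differed between replicates 2 and 3 than between E5 and E6. In their 4 libraries, with stage as the block, 1324 genes passed edgeR's test between replicate 3 and replicate 2 (adjusted p under 0.05), 821 higher and 503 lower in replicate 3, against 152 genes between the stages with replicate as the block. Of these 1324 genes, 270 differed by at least 2-fold. The widest difference among genes at a mean of at least 5 CPM was in a gene at 304 and 286 CPM in replicate 3 of E5 and E6 and at 13.5 and 11.5 CPM in replicate 2. Of the 152 stage calls, 33 were also among the 1324, against 17.1 for independent lists; both lists come from the same 4 libraries. The labels do not say whether a number stands for a day, a batch of eggs or a sequencing run, and no biological explanation was tested.

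Of pairs 2 and 3, pair 3 held a small set of genes that differed widely between the stages. Among the 9796 genes with a mean of at least 5 CPM in replicates 2 and 3, 12 were at least 4-fold higher at E6 than at E5 in pair 3, by 2.22 to 4.04 on the log2 scale, and 0 were 4-fold lower. None of the 12 passed edgeR's test with the block in either set of libraries, and 10 of them were lower at E6 in pair 2. E6 replicate 3 was the highest of the 4 libraries for all 12 and E5 replicate 3 the lowest for 11. This order, and that of their medians, follows largely from choosing the 12 by their difference in pair 3. Their median was 2.21 CPM in E5 replicate 3, 5.93 in E6 replicate 2, 7.62 in E5 replicate 2 and 20.7 in E6 replicate 3. In pair 2, 0 genes were 4-fold higher and 2 were 4-fold lower. In pair 1, with far fewer counts, 857 of the same 9796 genes were 4-fold higher and 1703 were 4-fold lower. There, 1 count in a library against 0 in its partner is enough to pass the 4-fold threshold, in either direction. How many of the 857 and 1703 rest on so few counts was not tallied. These numbers therefore do not tell whether pair 1 holds wide differences beyond counting error.

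The 2 replicate 1 libraries resembled each other across stages more than they resembled the other 4. Low depth alone is argued against, since E5 replicate 2 thinned at random to 585803 counts kept a correlation of at least 0.953 with E5 replicate 3 over 100 thinnings, against 0.55 for E5 replicate 1. Identifiers displaced by a constant number of positions are argued against, since the rank correlation of E5 replicate 1 with the mean of the other libraries was highest at an offset of 0 (0.59, with 0.17 the highest at any other offset up to 200), and stage is argued against because both stages show the pattern, with 0.56 the highest correlation of a replicate 1 library with its own stage. A candidate explanation that stays open is that reads of replicate 1 were counted on the opposite strand, which needs a kit that marks strand (not stated in the labels) and needs the 1000 genes most abundant elsewhere to lose most of their share. They held at most 11.5% in replicate 1 against at least 49.7% elsewhere, but the strand and position of the genes, needed to decide it, were not used here, and RNA of another source stays open, untested.

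All 10 splits of the 6 libraries into 3 and 3 gave 0 genes without a block, and 10 splits are too few for a share under 0.05. The fit without a block also called 0 of the 200 changed genes in simulated counts, so the 0 of the real split decides nothing. With the replicate block there are 4 splits that part every pair; the real one gave 28 genes, the highest other gave 34, and 2 of the 4 gave at least as many as the real one, again too few splits for a share under 0.05. The split with 34 differs from the real one only in which replicate 1 library counts as E5, and the remaining splits, which swap pair 2 or pair 3, gave 2 genes each. For replicates 2 and 3 alone, swapping 1 pair gave 0 genes against 152. This is the only other split there, and it puts the real stage difference into the residual spread, which lowers its count. The 0 is thus no measure of false calls among the 152. The splits of 6 libraries that swap pair 2 or pair 3 share this limit.

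A hypothesis was that replicate 1 carries the same stage difference as replicates 2 and 3. Of the 152 genes called from replicates 2 and 3, 53 had at least 10 counts in the replicate 1 libraries together, and 23 of these (43.4%, exact 95% interval 29.8% to 57.7%, two-sided exact binomial p = 0.41) moved the same way from E5 to E6 in replicate 1. The interval includes 50%, which was set beforehand as the result against the hypothesis; since it reaches 57.7%, a slight excess is not excluded and the question stays open. Genes are not independent replicates, and the low counts of replicate 1 limit this test.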
